A study of Homo sapiens with 54 samples.

How the data were processed

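The data are bulk RNA-seq of 54 human esophageal mucosal biopsies from 27 donors, 8 healthy controls (HC) and 19 people with eosinophilic esophagitis (EoE). Each donor gave 1 biopsy of the proximal and 1 of the distal esophagus, so that there are 4 groups, and the same replicate number names the same donor in both regions of a disease state. The design text counts 20 EoE patients, and files of 19 were used here. Per the labels' protocols, biopsies were homogenised in lysis buffer, total RNA was extracted on columns, and directional mRNA libraries were made. Per the submitters' processing notes, the tools used before deposit were cutadapt 1.13, STAR, HTSeq 0.6.1p1 and DESeq2 1.14.1 with the genome build hg38, and neither their roles, the annotation release nor the strand setting of the counting is stated.

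The deposited files hold raw read counts, 1 whole number per Ensembl gene, for the same 58395 genes in each library, with no lines for unassigned reads. Totals per library ranged from 15969656 to 32576606 counts. Gene symbols came from a table of gene names that matched 57754 of the identifiers, and gene types, coordinates, GC content and exon length from GENCODE 29 on hg38, which matched 58275 of them and missed 120. All 13 mitochondrially encoded genes had 0 counts in every library, so their share could not be used as a measure of RNA quality. Because the strand setting is not stated, values of genes that share exon positions with another gene are uncertain, whether or not the text marks them, as are those of genes with near-identical copies or processed pseudogenes. Among the genes named, ALDOA, BCL3, CD79B, FAM25A, IL1RL1, IRGQ, PDF, PEG3, PTGDR2, RAD54L2, RPS10, SMPD3 and SRXN1 share positions with a gene on the same strand, and ANO1, CDH1, CISH, DKK1, DSG1, ENDOG, FLG, IGFL1, ITGAL, KRT8, LOX, MX1, RELA, SIGLEC6, SLC26A4, TPGS1 and TSLP with one on the opposite strand only.

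Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM normalisation, filterByExpr at its default settings by group, and the quasi-likelihood F test, two-sided. A gene is said to be called, to have risen or to have fallen where its Benjamini-Hochberg adjusted p is under 0.05 over all genes tested in that comparison. The standard error of a log2 fold change was computed from the fold change and its F statistic. EoE was compared with healthy in each region on its own, so that no donor entered a fit with 2 libraries. Distal was compared with proximal with the donor as a block, in healthy and in EoE donors. A further fit of all 54 libraries, with the donor as a block, tested whether the difference between EoE and healthy was itself different in the distal and the proximal esophagus. The block follows from the design text, which says that both biopsies came from each person. As a check, deviations from the group means of the 2000 most variable genes correlated between the 2 biopsies of a donor with r over 0.1 in 8 of 8 healthy and 17 of 19 EoE donors (medians 0.578 and 0.792). The lowest r was 0.498 in healthy and -0.083 in EoE donors. Within a disease state, a distal biopsy matched its own donor's proximal biopsy best in 8 of 8 healthy and 14 of 19 EoE donors. The fits and the sign of their fold changes were tested on simulated counts drawn from the real means and library sizes with a known set of changed genes. In the simulation of the distal comparison of EoE with healthy, run on 17340 genes, 80% of genes changed 2-fold were recovered and 3.5% of the calls were false. In that of the healthy distal and proximal biopsies, run on 15943 genes, these were 80% and 5.2%. Each size of change was given to 50 genes, all other genes were kept equal, and no donor effect or GC trend was simulated. These rates therefore do not cover large shifts in composition, GC trends or differences between donors.

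Expression levels are given as CPM, counts scaled to the same library total of 1e6, computed from the deposited counts, as mean ± SD over a group, and a fold change as its log2 value ± standard error. The ratio of a gene with 1 to 3 counts over all healthy libraries of a region is given with its 95% counting interval. Where those libraries held 0 counts, a lower bound against a floor of 3 counts summed over the group is given. Intervals and floors cover counting error only, not the spread between people.

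The genes named in the text follow a rule written before the data were examined. It takes 20 fixed genes of the disease, the 6 largest rises and 6 largest falls among called protein-coding genes with a mean log2 CPM of at least 1 (in the disease comparisons only genes with the same sign in the other region), the 5 smallest p-values in each direction for the difference of the disease effects, and up to 3 members of each gene list. Genes on the Y chromosome, XIST, HLA genes, antigen receptor segments and genes that some people lack were never named, and some genes that the rule takes are not reported here. A total of 30 lists of marker and pathway genes were written at the same time. For each list the members that rose or fell were counted, over all genes tested and adjusted over the list alone. Such a count is to be read against the share of all genes that rose or fell in the same comparison. Each list was also tested with camera from limma 3.58.1 on log2 CPM (prior count 2), with its preset and again with an estimated correlation between genes, and with fry. Results of fry are not reported here. List scores are the mean log2 CPM of the tested members, compared by permutation tests with 100000 resamples, two-sided.

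Alternatives chosen before the data were examined were DESeq2 1.42.0, limma-trend, a limma-voom fit of all libraries with the donor as a random effect, other size factors, no filter or a stricter filter on low counts, fits with or without the block, and leaving out each healthy donor (each EoE donor for the comparison of regions in EoE) in turn. After the data were seen, fits were added with a correction of each library for its trend with GC content and gene length, with protein-coding genes that have no named processed pseudogene, and with the distal libraries thinned to the smallest total. Each count of called genes was also compared with the counts from regrouped donors or swapped regions. The number of regroupings for the difference of the disease effects was lowered to 25 to shorten the computation, after a longer run had been seen in which no other grouping called a gene. Other computing used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The mouse experiments that the series title describes are not analysed here. As a check for mixed-up samples, sex-linked expression was compared between the 2 libraries of each donor, and 0 of 27 donors disagreed.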

Results

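Gene expression was measured by bulk RNA-seq in mucosal biopsies of the proximal and the distal esophagus. Eosinophilic esophagitis (EoE) is a chronic allergic disease in which eosinophils enter the esophageal epithelium. There were 4 groups, with 8 proximal and 8 distal biopsies of healthy donors and 19 proximal and 19 distal biopsies of EoE donors. Total counts were 18270205 ± 2280000 (mean ± SD, n = 8) in healthy distal, 21936401 ± 3330000 (n = 19) in EoE distal, 20507346 ± 3880000 (n = 8) in healthy proximal and 26621241 ± 3300000 (n = 19) in EoE proximal libraries. The EoE libraries were deeper than the healthy ones in both regions (permutation tests, p = 0.009 distal and p = 0.00023 proximal). The 20 most abundant genes, among them the keratins KRT4 and KRT13 and the cornified envelope gene SPRR3, took 29.98 ± 1.46% of the counts in healthy distal and 19.1 ± 6.46% in EoE distal libraries (permutation test, p = 0.00017). In proximal libraries that share was 29.3 ± 3.18% in healthy and 20.76 ± 6.33% in EoE donors (permutation test, p = 0.0015). No sequencing batch or date is used here, since the labels give none. Libraries also differed in how counts followed the GC content and the length of genes. The slope of a library's log2 deviation per 10 points of GC was -0.145 ± 0.0456 in EoE distal libraries, negative in 19 of 19. It was 0.0688 ± 0.0375 in healthy distal, 0.0562 ± 0.0727 in EoE proximal and 0.142 ± 0.0388 in healthy proximal libraries. The slope per doubling of gene length was 0.0783 ± 0.0531 in EoE distal libraries, negative in 1 of 19. It was -0.0802 ± 0.0572 in EoE proximal libraries, negative in 18 of 19. In healthy libraries it was 0.00887 ± 0.0318 in distal and -0.004 ± 0.0338 in proximal ones. The trend with GC content separates the EoE distal libraries from the healthy ones in the same way as the disease does. A processing batch and the groups can therefore not be told apart from the labels.

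**Figure D1:**
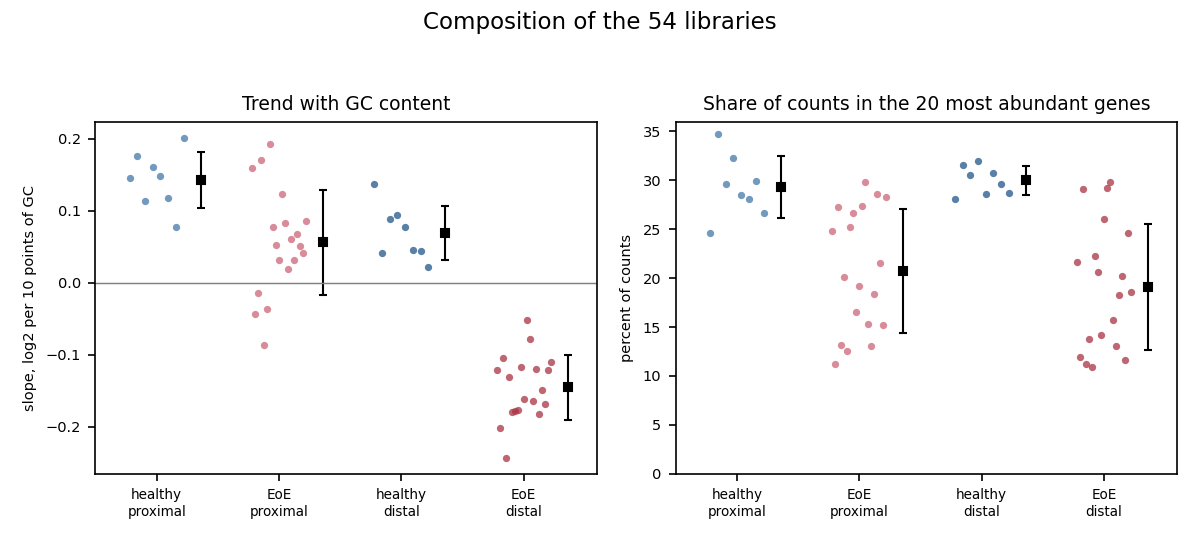
Composition of the 54 libraries, with 1 point per library and the mean and SD of each group as a black square and bar. The left panel shows the slope of log2 expression per 10 points of GC content, which was below 0 in 19 of 19 EoE distal libraries, and the right panel the percent of counts in the 20 most abundant genes, with a mean of 29.98% in healthy distal and 19.1% in EoE distal libraries.

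The distal comparison asked which genes differ between EoE and healthy mucosa near the stomach. Among the largest rises were those of genes that respond to the cytokine IL-13 in epithelium. The eosinophil chemoattractant CCL26 averaged 107 ± 163 CPM in the 19 EoE libraries and 0.683 ± 0.357 CPM in the 8 healthy ones (log2 fold change 7.29 ± 1.3, adjusted p = 6.8e-05), and the lipoxygenase ALOX15 averaged 481 ± 725 against 0.751 ± 0.307 CPM (9.29 ± 1.7, adjusted p = 9.2e-05). Both were above every healthy library in 17 of 19 EoE libraries. The mast cell protease CPA3 rose from 3.72 ± 2.23 to 79.6 ± 66.3 CPM and was higher in 19 of 19 EoE libraries than in any healthy one (4.41 ± 0.61, adjusted p = 4.4e-06). The desmosomal cadherin DSG1, which holds the upper cell layers together, fell from 203 ± 74.6 to 35.9 ± 41 CPM (-2.51 ± 0.43, adjusted p = 5.1e-05) and was below every healthy library in 17 of 19.

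Of 17573 genes tested, 7896 were called, 4154 higher and 3742 lower in EoE, and 1755 of them changed at least 2-fold (967 higher, 788 lower). The balance depends on the method, since limma-voom with the donor as a random effect called 3595 higher and 4167 lower. Among the IL-13-responsive genes 19 of 20 rose and 0 fell (19 adjusted over the list alone). They include the cadherin CDH26 (438 ± 291 against 7.01 ± 2.75 CPM, adjusted p = 4.2e-07), the matricellular protein POSTN (192-fold, adjusted p = 8.4e-05), the chloride channel ANO1 (23.4-fold, adjusted p = 1e-05) and the esophageal calpain CAPN14 (3.14-fold, adjusted p = 0.00024). The hyaluronan-binding protein TNFAIP6 averaged 132 ± 194 CPM in EoE and 0.127 ± 0.103 CPM in healthy libraries, and 15 of 19 EoE libraries were above every healthy one. Other large rises were those of the anion exchanger SLC26A4 (218-fold) and the cytokine IL19 (226-fold). IL13 itself had 765 counts over the EoE libraries and 0 over the healthy ones, at least 89.4-fold higher. LRRC31 had 2 counts over the healthy libraries, a ratio of 1290 with a 95% counting interval of 358 to 10700, and TGM6 had 1 count, a ratio of 1270 (227 to 50000).

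All 14 mast cell markers rose, MS4A2 by 11.7-fold and SIGLEC6 by 12.9-fold, as did 5 of 6 eosinophil markers, with SIGLEC8 at 8.83-fold, and the counts adjusted over the list alone were the same. The Charcot-Leyden crystal protein CLC, abundant in eosinophils, had 1137 counts over the EoE and 1 over the healthy libraries, a ratio of 399 (71.6 to 15700). The eosinophil peroxidase gene EPX was too low to be tested, at 0.129 ± 0.0857 CPM in EoE and 0.167 ± 0.0547 CPM in healthy libraries. IL5 was also not tested, with 184 counts against 1 and a ratio of 64.5 (11.6 to 2550). T cell markers rose in 16 of 19 cases (18 adjusted over the list alone), CD3D by 2.89-fold. Cytotoxic lymphocyte markers rose in 11 of 12 (11 adjusted over the list alone), led by GZMB at 6.19-fold. Type 2 cytokines and receptors rose in 10 of 13 (10 adjusted over the list alone), among them IL1RL1, the receptor of IL-33, at 15.3-fold, an estimate that is uncertain because IL18R1 overlaps the gene. The epithelial alarmin TSLP was at 6.78 ± 2.48 CPM in EoE and 5.24 ± 2.31 CPM in healthy libraries (adjusted p = 0.19).

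Squamous differentiation genes were lower. Of 29, 16 fell and 0 rose (21 fell adjusted over the list alone), and SPRR3 was below every healthy library in 19 of 19 EoE libraries (12500 ± 9260 against 39200 ± 6550 CPM). The envelope precursor IVL fell by 1.10 on the log2 scale (adjusted p = 0.0015) and the cornulin gene CRNN by 1.21 (-1.21 ± 0.49, adjusted p = 0.048). Filaggrin, FLG, was at 222 ± 286 against 626 ± 248 CPM and did not pass (adjusted p = 0.07). With the correction for GC content and gene length, 8 of the 29 fell. Cell cycle genes rose in 18 of 24 cases (21 adjusted over the list alone), MKI67 by 2.02-fold and CENPF by 2.07-fold. Interferon response genes rose in 16 of 23 (17 rose and 1 fell adjusted over the list alone), with IFI27 at 6.34-fold and MX1 at 2.01-fold. With camera's preset correlation 9 of 28 lists passed: mast cell, eosinophil, T cell and cytotoxic lymphocyte markers, type 2 cytokines and receptors, IL-13-responsive, cell cycle and interferon response genes upward, and squamous differentiation genes downward. With an estimated correlation none of the 9 held, with an adjusted p = 0.692 for the cell cycle and interferon lists and an adjusted p = 0.548 for each of the others. The scores of the same 9 lists did differ between EoE and healthy libraries (permutation tests, adjusted p = 0.00019 to 0.012). Those tests compare the groups and do not set a list against other genes, as camera does. The largest falls named by the rule were those of the metallothionein MT1A (-5.06 ± 0.82), of EDN3, which encodes endothelin 3 (-5.01 ± 0.62, adjusted p = 9.4e-07), and of the laminin chain LAMB4 (-4.83 ± 0.54, adjusted p = 2.1e-07), the latter 2 below every healthy library in 19 of 19. The metallothioneins MT1M (-3.97 ± 0.75) and MT1H (-3.66 ± 0.86) fell too, and reads of all 3 could be shared by near-identical family members. The hair keratin-associated gene KRTAP3-2 fell by 4.06 on the log2 scale. IKBKB, which encodes the kinase that the series title names, was at 61 ± 9.77 CPM in EoE and 58.4 ± 7.4 CPM in healthy distal libraries (log2 fold change 0.06 ± 0.091, adjusted p = 0.63).

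**Figure D2:**
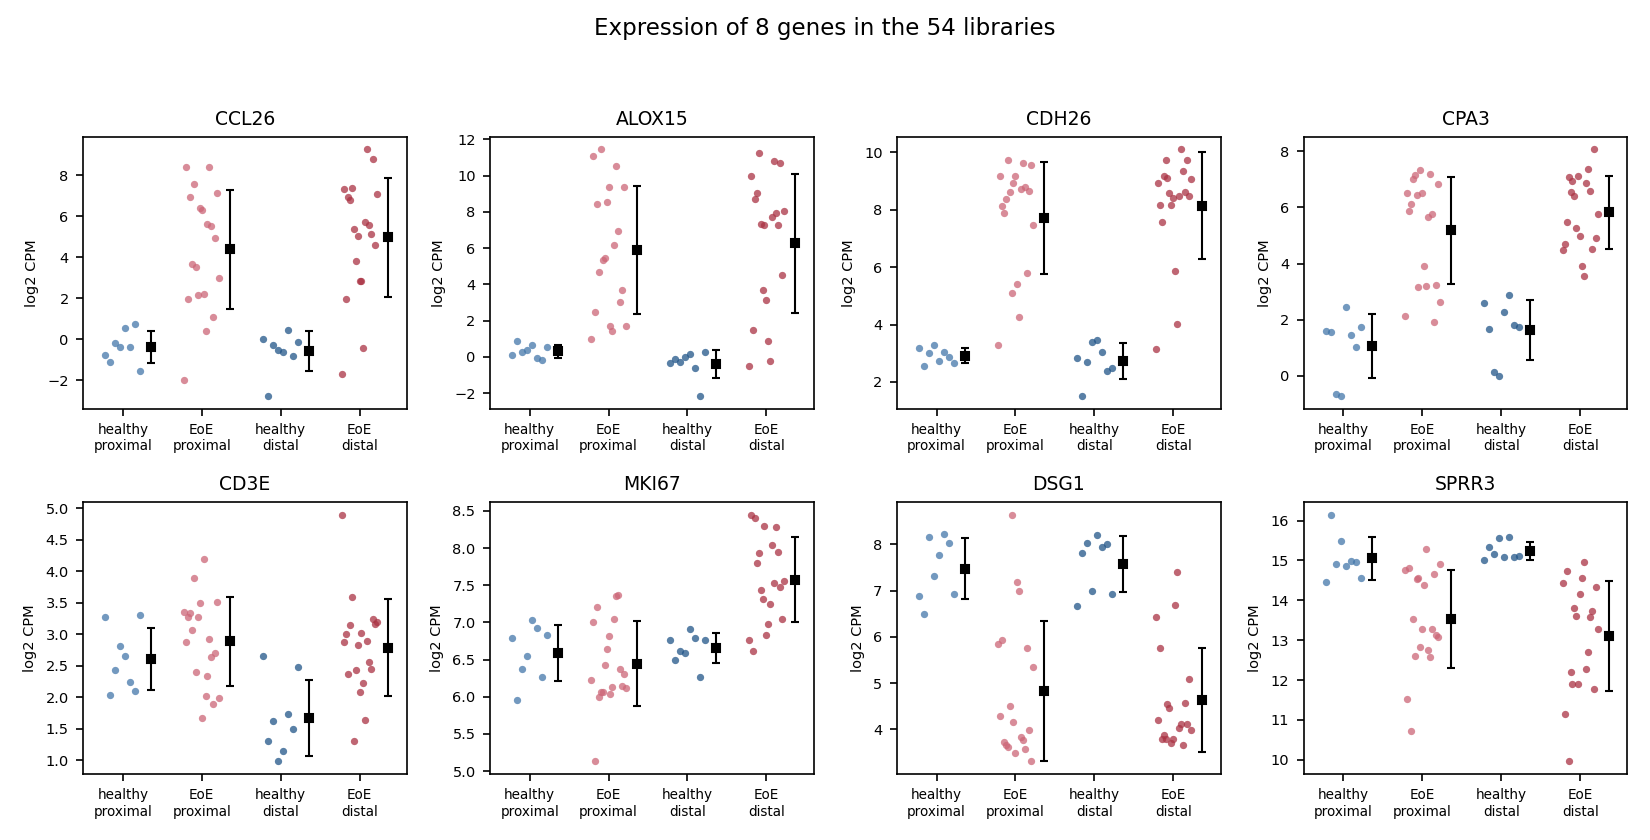
Expression of 8 genes in log2 CPM in the 54 libraries, with 1 point per library, in healthy proximal, EoE proximal, healthy distal and EoE distal biopsies; black squares and bars are the mean and SD of each group. CPA3 lies above every healthy distal library in 19 of 19 EoE distal libraries, and SPRR3 below every one in 19 of 19.

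The proximal comparison asked the same of mucosa far from the stomach. CCL26 averaged 77.2 ± 107 CPM in the 19 EoE and 0.784 ± 0.477 CPM in the 8 healthy libraries (6.58 ± 1.3, adjusted p = 0.0018). ALOX15 averaged 467 ± 812 against 1.19 ± 0.33 CPM and was above every healthy library in 19 of 19 EoE libraries (8.63 ± 1.7, adjusted p = 0.0019). CDH26 averaged 364 ± 272 against 7.59 ± 1.37 CPM (5.58 ± 0.74, adjusted p = 9e-05). FLG, which binds keratin filaments in the upper layers, fell from 933 ± 608 to 192 ± 192 CPM (-2.29 ± 0.62, adjusted p = 0.012) and lay below every healthy library in 17 of 19.

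Of 17987 genes tested, 4211 were called, 2489 higher and 1722 lower in EoE, and 885 changed at least 2-fold (613 higher, 272 lower). Here too the balance depends on the method, since limma-voom with the donor as a random effect called 2021 higher and 2331 lower (317 and 677 by at least 2-fold). All 14 mast cell markers rose (14 adjusted over the list alone), among them TPSAB1 at 20.6-fold, whose reads its near-identical copy TPSB2 could share, and CTSG at 38.8-fold. IL-13-responsive genes rose in 18 of 20 cases (19 adjusted over the list alone) and eosinophil markers in 6 of 7 (6 adjusted over the list alone). CAPN14 rose 2.49-fold. On the log2 scale POSTN rose by 7.31 ± 1.6 and TNFAIP6 by 9.15 ± 2.1. IL13 had 849 counts over the EoE libraries and 0 over the healthy ones, at least 91.8-fold higher, CLC a ratio of 305 (84.4 to 2520), LRRC31 a ratio of 1110 (308 to 9200) and IL5, not tested, a ratio of 22.4 (7.66 to 109). Macrophage and monocyte markers rose in 7 of 13 cases (9 adjusted over the list alone), with the mannose receptor MRC1 at 7.02-fold. Type 2 cytokines and receptors rose in 6 of 12 (8 adjusted over the list alone), with the signalling suppressor CISH at 5-fold. T cell markers rose in 1 of 19 cases (1 adjusted over the list alone), the costimulator ICOS at 2.68-fold, and cytotoxic lymphocyte markers in 3 of 12 (3 adjusted over the list alone). Cell cycle genes rose in 6 of 24 (8 adjusted over the list alone). Squamous differentiation genes fell in 9 of 29 and rose in 0 (15 fell adjusted over the list alone), DSG1 from 194 ± 82.6 to 55.7 ± 91.7 CPM (-1.80 ± 0.57, adjusted p = 0.024) and the envelope protein EVPL by 0.61 on the log2 scale. CRNN (-0.99 ± 0.44, adjusted p = 0.1) and the protease inhibitor SPINK7 (-1.38 ± 0.56, adjusted p = 0.071) did not pass. SPINK7 fell in distal biopsies (-1.58 ± 0.64, adjusted p = 0.046). Other large falls were those of KRTAP3-2 (-3.87, where 1 healthy library was at 8.08 log2 CPM and the other 7 at 0.18 to 3.83), the crystallin CRYM (-2.18), IGFL1 (-1.93) and ZBED2 (-1.91). TSLP (0.65 ± 0.25, adjusted p = 0.056) and IKBKB (-0.12 ± 0.064, adjusted p = 0.17) were not called. Camera with its preset correlation passed 9 of 29 lists, the mast cell, eosinophil, IL-13-responsive, type 2, macrophage, T cell, cytotoxic lymphocyte and cell cycle lists upward and the squamous list downward. None held with an estimated correlation (lowest adjusted p = 0.489, with adjusted p = 0.715 for the cell cycle, adjusted p = 0.685 for T cell and cytotoxic markers and adjusted p = 0.522 for macrophage markers). In permutation tests of their scores, T cell markers (adjusted p = 0.11) and cell cycle genes (adjusted p = 0.17) did not pass. The other lists among the 9 did (adjusted p = 0.00047 to 0.042).

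**Figure D3:**
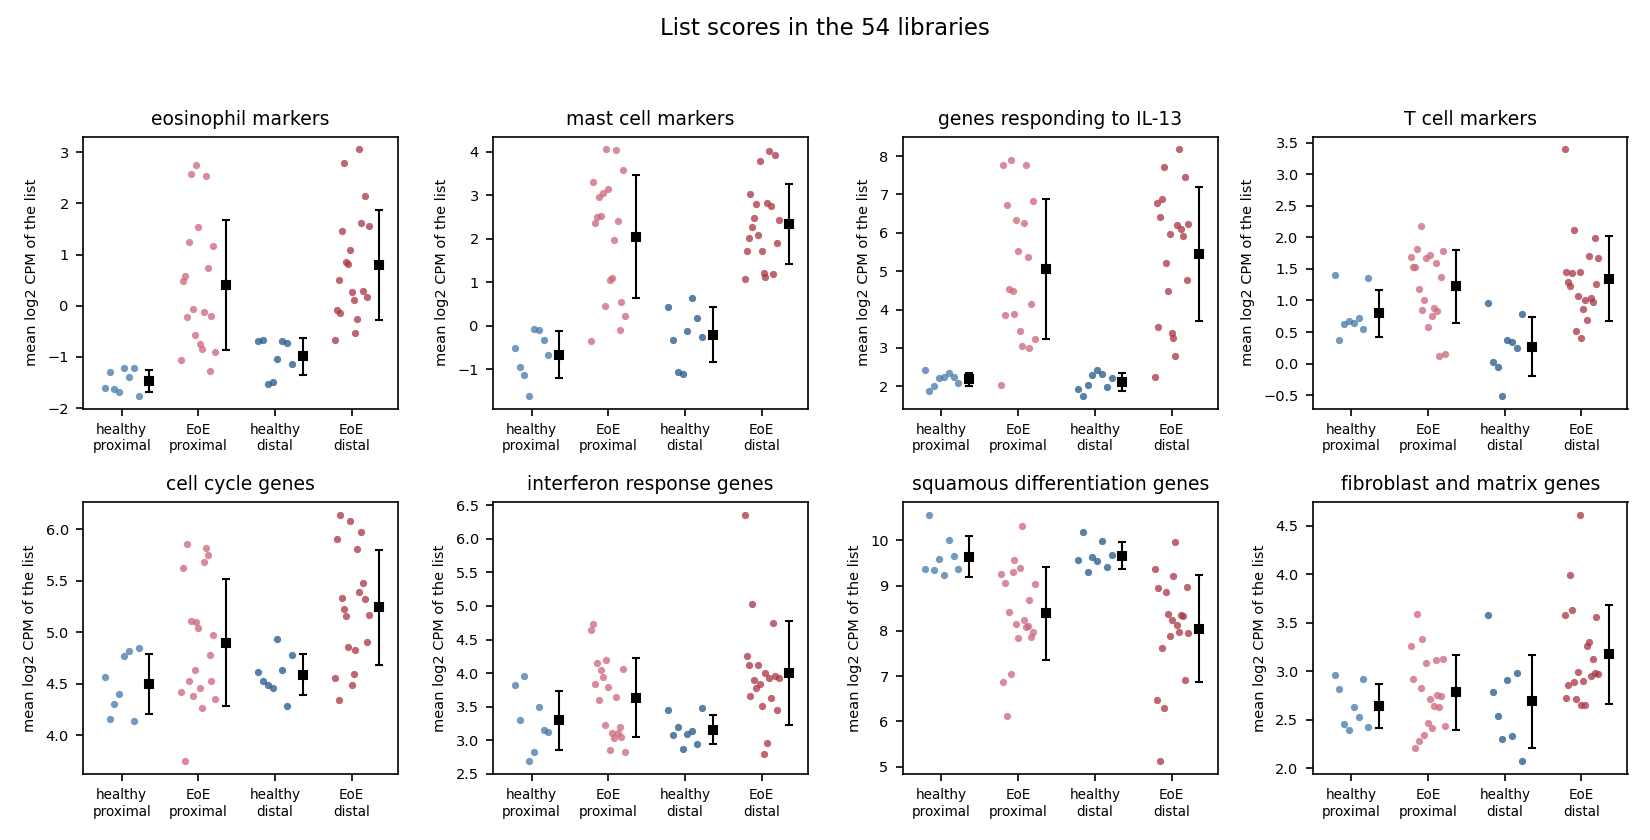
Scores of 8 gene lists, the mean log2 CPM of a list's members, in the 54 libraries, with 1 point per library and black squares and bars for the mean and SD of each of the 4 groups. The mast cell score was 2.54 higher in EoE than in healthy distal libraries and 2.72 higher in proximal ones, and the squamous differentiation score fell by 1.61 and by 1.26.

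The effects of EoE in the 2 regions were then set side by side. Across 17270 genes tested in both, which are not independent replicates, the log2 fold changes correlated with r = 0.834 and rho = 0.708. The same donors enter both comparisons, and permuting the donors' disease labels gave a median r of 0.524 (0.149 to 0.829) and a median rho of 0.462 (0.0146 to 0.777), so that the observed rho lies within the permuted range. Among 13150 genes with a mean log2 CPM of at least 1, r was 0.864, also within the permuted range (0.172 to 0.886). Genes called higher in both regions numbered 1661 and those called lower in both 966, and 185 were called in opposite directions. The covariance was 0.397, against a median of 0.0396 and a highest value of 0.154 under permuted labels. With separate donors for the 2 regions, r was 0.599 and 0.732 (covariance 0.281 and 0.457).

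Across the 19 EoE donors, list scores of the 2 biopsies were compared in a family of 8 relations, with 4 further ones chosen after their values were seen. The squamous differentiation score of a donor's distal biopsy followed that of the proximal one, with r = 0.883 (permutation p = 1e-05, the smallest they can give; adjusted p = 8e-05) and rho = 0.756 (permutation p = 0.00022), and r = 0.792 without the 2 donors farthest from the median. The eosinophil scores of the 2 biopsies gave r = 0.575 (permutation p = 0.011, adjusted p = 0.015) and rho = 0.498 (permutation p = 0.032). The size of this relation depends on 2 donors, since r was 0.279 without the 2 farthest from the median. Leaving out such donors also narrows the range, which can by itself lower r. Eosinophil scores rose with mast cell scores, with r = 0.667 in distal (permutation p = 0.002, adjusted p = 0.0032; rho = 0.616, permutation p = 0.0062; r = 0.643 without 2 donors) and r = 0.834 in proximal biopsies (permutation p = 2e-05, adjusted p = 8e-05; rho = 0.867, permutation p = 2e-05; r = 0.873 without 2 donors). They also rose with the score of IL-13-responsive genes, with r = 0.718 in distal (permutation p = 0.00054, adjusted p = 0.0011; rho = 0.637, permutation p = 0.0038; r = 0.592 without 2 donors) and r = 0.752 in proximal biopsies (permutation p = 0.0003, adjusted p = 0.0008; rho = 0.795, permutation p = 0.00012; r = 0.716 without 2 donors). Against the squamous differentiation score, the eosinophil score gave r = -0.331 in distal (permutation p = 0.16, adjusted p = 0.16; rho = -0.426, permutation p = 0.069; r = -0.226 without 2 donors) and r = -0.472 in proximal biopsies (permutation p = 0.04, adjusted p = 0.046; rho = -0.530, permutation p = 0.022; r = -0.415 without 2 donors). With members scaled to equal weight the proximal value no longer passed (adjusted p = 0.061).

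The paired biopsies of the 8 healthy donors asked how the distal and the proximal esophagus differ without the disease. T cell markers were lower in the distal biopsies. CD3E, a part of the T cell receptor complex, averaged 3.38 ± 1.61 CPM in distal and 6.34 ± 2.28 CPM in proximal biopsies (-0.92 ± 0.15, adjusted p = 0.0021) and was higher in the distal biopsy in 0 of 8 donors. CD8A fell from 7.79 ± 1.42 to 3.35 ± 1.8 CPM (-1.29 ± 0.29, adjusted p = 0.013), and the leukocyte integrin ITGAL from 7.34 ± 1.61 to 3.51 ± 1.63 CPM (-1.10 ± 0.14, adjusted p = 0.00035), both in 8 of 8 donors. Of 14 T cell markers tested, 10 fell and 0 rose (12 fell adjusted over the list alone), ZAP70 among them. Macrophage and monocyte markers went the other way, with 4 of 12 risen (4 adjusted over the list alone), C1QA by 1.33-fold and CSF1R by 1.22-fold, and 2 of 8 mast cell markers rose (4 adjusted over the list alone).

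Of 16113 genes tested, 2152 were called, 974 higher and 1178 lower in distal biopsies, and 188 changed at least 2-fold (81 higher, 107 lower). Leaving out 1 donor gave 1364 to 2624 calls, and without HC replicate 2 more were higher (1355) than lower (1269). The largest rises named by the rule were those of FAM25A (12.1-fold) and the glycolytic enzyme ALDOA (4.32-fold), and the largest fall was that of the ribosomal protein gene RPS10 (-2.59 ± 0.14), each in 8 of 8 donors. These are uncertain, because FAM25A has near-identical copies, another gene overlaps ALDOA and RPS10 each on the same strand, and RPS10 lay at only 6.85 ± 1.09 CPM in proximal biopsies. The inducible prostaglandin synthase PTGS2 (3.63-fold, adjusted p = 0.041), the Wnt inhibitor DKK1 (2.59-fold), the imprinted gene PEG3 (2.58-fold, overlapped by ZIM2) and the immediate early gene EGR1 (2.48-fold, adjusted p = 0.042) also rose. PTGS2 did not pass after the correction for GC content and gene length (adjusted p = 0.065). SRXN1 (-1.51 ± 0.18), RND1 (-1.47 ± 0.25) and the interleukin-7 receptor IL7R (-1.24 ± 0.3, adjusted p = 0.019) fell. Hypoxia response genes rose in 5 of 19 cases (5 adjusted over the list alone), and erythrocyte markers fell in 2 of 3 (3 adjusted over the list alone). Camera with its preset correlation passed 6 of 27 lists, T cell, cytotoxic lymphocyte and erythrocyte lists downward and hypoxia, macrophage and mast cell lists upward. None held with an estimated correlation (adjusted p = 0.373 for T cell, adjusted p = 0.58 for mast cell, adjusted p = 0.601 for hypoxia, adjusted p = 0.61 for cytotoxic and erythrocyte and adjusted p = 0.697 for macrophage lists). Processed pseudogenes differed between the regions as well. Of 18903 genes in all libraries, 84 separated every distal from every proximal library, and 56 of these (66.7%) were processed pseudogenes, against 10.7% of all genes (Fisher's exact test, p = 1.8e-34). Protein-coding genes that have a named processed pseudogene made up 8.3% of the 84 and 9.1% of all. The 84 are mostly pseudogenes, which cannot count as such parent genes, so that these shares are not comparable. Of the parent genes tested in healthy donors, 18.3% were called. Processed pseudogenes were called more often than protein-coding genes without a named one (31.7% against 11.3%), and a fit of the latter alone called 1101 genes, 30 of them changed at least 2-fold (8 higher, 22 lower).

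The distal and proximal biopsies of the 19 EoE donors were compared in pairs. COL12A1, a collagen that sits on fibrils, averaged 10.4 ± 12.4 CPM in distal and 2.66 ± 1.62 CPM in proximal biopsies and was higher in 19 of 19 donors (1.62 ± 0.18, adjusted p = 7.8e-08). The proliferation marker MKI67 was higher by 2.19-fold (adjusted p = 2.2e-08), and E-cadherin, CDH1, 562 ± 55.1 against 337 ± 32.4 CPM (0.74 ± 0.043, adjusted p = 4.5e-12), both higher in 19 of 19 donors. EDN3 was lower, at 0.481 ± 0.689 against 4.27 ± 7.71 CPM (-2.77 ± 0.47, adjusted p = 4.2e-05), and was higher in the distal biopsy in 2 of 19.

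Of 17329 genes tested, 9694 were called, 4716 higher and 4978 lower in distal biopsies, and 616 changed at least 2-fold (148 higher, 468 lower). Fibroblast and matrix genes rose in 15 and fell in 1 of 25 cases (16 and 1 adjusted over the list alone), COL6A3 by 2.51-fold, FBN1 by 2.28-fold and LUM by 2.01-fold. Theirs was the single list of 28 that camera passed with the preset correlation (adjusted p = 0.0305), and it did not hold (adjusted p = 0.973 with an estimated correlation). Cell cycle genes rose in 12 and fell in 1 of 24 (13 and 1 adjusted over the list alone), with CENPF at 1.83-fold, and endothelial markers rose in 8 and fell in 2 of 17 (8 and 2 adjusted over the list alone), with FLT1 at 2.01-fold. With rises and falls together, both lists were called about as often as all genes (9694 of 17329), though most of their calls were rises. Junction genes rose in 13 and fell in 6 of 22 (13 and 6 adjusted over the list alone), with DSC3 and DSP at 1.57-fold and 1.55-fold. Squamous differentiation genes fell in 8 and rose in 2 of 29 (7 and 2 adjusted over the list alone). No eosinophil or mast cell marker was called, out of 7 and 14, with edgeR at an adjusted p under 0.05. Other large rises were those of the kinase POMK (3.67-fold), the transcription factors ZFHX4 (3.31-fold) and TBX3 (2.91-fold), the collagen COL6A5 (2.86-fold) and the mucin MUC16 (2.65-fold). TMEM238 (-2.79 ± 0.075), ENDOG (-2.87 ± 0.11), TPGS1 (-2.42 ± 0.13), CRISP3 (-2.56 ± 0.69) and PDF (-2.94 ± 0.13, overlapped by COG8) fell. The fold changes followed the GC content of genes (r = -0.557 across genes) and their length (r = 0.489). After correction, 7484 genes were called, 369 of them changed at least 2-fold (147 higher, 222 lower). Of 5686 genes called in both fits, 5224 had the same sign and the others the opposite one. COL12A1 and COL6A3 still rose after the correction, by 1.25 ± 0.18 and 1.12 ± 0.18 on the log2 scale, against 1.62 and 1.33 before. With the correction TMEM238 fell by 1.53, the stress genes HSPB1 (-0.71 to -0.08) and JUND (-1.12 to -0.18) moved towards 0, and BCL3 (-0.62 to 0.17) and IRF7 (-0.47 to 0.28) changed sign.

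**Figure D4:**
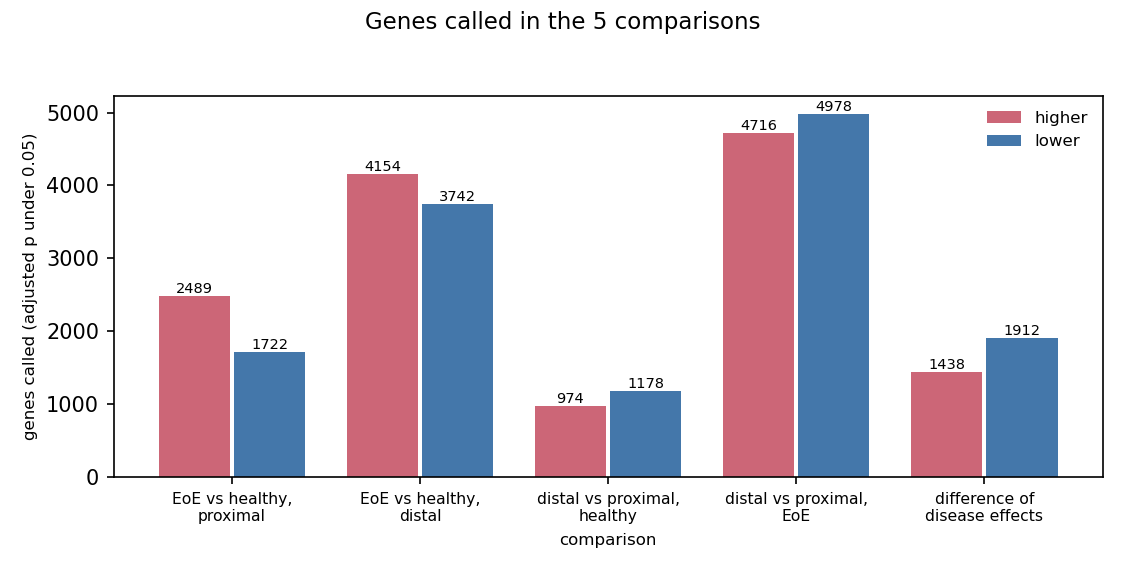
Number of genes called higher (red) and lower (blue) in each of the 5 comparisons, at an adjusted p under 0.05 from edgeR. The largest total is that of the paired comparison of regions in EoE donors, with 4716 genes higher and 4978 lower in distal biopsies.

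The fit of all 54 libraries tested whether the disease effect differs between the regions. EDN3 and LAMB4, which were lower in EoE, differed by -2.92 ± 0.57 (adjusted p = 0.00051) and -2.65 ± 0.59 (adjusted p = 0.002) on the log2 scale, distal minus proximal. The disease effect on MKI67 was 1.07 ± 0.18 higher in distal biopsies (adjusted p = 0.0001), and that on the T cell genes CD3E (0.83 ± 0.29, adjusted p = 0.044) and CD3D (0.95, adjusted p = 0.048) was higher as well. For CD3E the regions differed in healthy donors (-0.92 ± 0.15, distal against proximal) and were not called different in EoE donors (-0.1 ± 0.16, adjusted p = 0.6). The mean T cell score was 0.27 in distal and 0.79 in proximal biopsies of healthy donors, and 1.35 and 1.22 in EoE. No difference was called for CCL26 (0.74, adjusted p = 0.73), ALOX15 (0.97, adjusted p = 0.72) or CPA3 (-0.04, adjusted p = 0.98).

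Of 18935 genes tested, 3350 were called, 1438 with a higher and 1912 with a lower disease effect in distal biopsies, and 366 differed at least 2-fold (92 higher, 274 lower). The smallest p-values belonged to the genes PRRC2C (0.87 ± 0.083), THRAP3 (0.60 ± 0.061), POU2F1 (0.81 ± 0.087), RAD54L2 (0.72 ± 0.078, overlapped by TEX264) and IRGQ (0.78 ± 0.085) upward. Downward they were the processed pseudogenes RPS19P1 (-1.85 ± 0.1), TPT1P4 (-1.72 ± 0.13), UQCRFS1P1 (-1.75 ± 0.14) and ENSG00000237214 (-0.94 ± 0.073), which can share reads with their parent genes, and TMEM238 (-1.90 ± 0.13). T cell markers rose in 4 of 20 cases (5 adjusted over the list alone), cell cycle genes in 5 of 24 (7 adjusted over the list alone), interferon response genes in 2 of 24 (0 adjusted over the list alone) and cytotoxic lymphocyte markers in 2 of 14 (0 adjusted over the list alone). The interferon count is near the share of all genes, 1438 of 18935. Camera with its preset correlation passed these 4 of 29 lists, T cell, cell cycle, interferon and cytotoxic (adjusted p = 0.000557, 0.0136, 0.0107 and 0.0147), and each had an adjusted p = 0.924 with an estimated correlation. Junction genes rose in 6 and fell in 2 of 22 (7 and 2 adjusted over the list alone), with DSP at 0.71 ± 0.12. The fold changes followed GC content (r = -0.422 across genes) and gene length (r = 0.451), and after the correction 1678 genes were called (92 higher and 115 lower by at least 2-fold). Of the 3350 genes called before, 1248 were called again, 1246 of them with the same sign. MKI67 (0.78, adjusted p = 0.0031) and CENPF (0.46, adjusted p = 0.041) were among the genes called after the correction, and CD3E (0.83, adjusted p = 0.069) was not. Differences of list scores between the regions passed for none of 28 lists (permutation tests, lowest adjusted p = 0.3), the T cell score having the lowest permutation p, 0.013.

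Coordinates on hg38 (GENCODE 29) are chromosome 7, 75769533 to 75789896 for CCL26 (ENSG00000006606); chromosome 17, 4630902 to 4642294 for ALOX15 (ENSG00000161905); chromosome 20, 59958427 to 60034011 for CDH26 (ENSG00000124215); and chromosome 3, 148865256 to 148897196 for CPA3 (ENSG00000163751). DSG1 (ENSG00000134760) lies on chromosome 18, 31318089 to 31357029, EDN3 (ENSG00000124205) on chromosome 20, 59300427 to 59325992, MKI67 (ENSG00000148773) on chromosome 10, 128096659 to 128126385, and CD3E (ENSG00000198851) on chromosome 11, 118304545 to 118316175. IL13 (ENSG00000169194) lies on chromosome 5, 132656263 to 132661110, and COL12A1 on chromosome 6, 75084326 to 75206051. The deposited counts are per gene, not per exon.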

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

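Of the tests weighed here, those of pseudogene read assignment and of GC content as the whole cause in healthy donors, of the share of non-epithelial cells, of GC content as the whole cause in the distal disease comparison and of FTH1 against squamous genes were chosen after the results they measure were seen, as were all GC-corrected fits and FTH1 itself.

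The first pattern is the healthy distal and proximal biopsies, with 2152 genes called and T cell markers lower in distal tissue. The T cell list passed camera with its preset correlation but not with an estimated one (adjusted p = 0.373). Of 100 regroupings that swap the regions within donors, 1, the real one, called as many genes (highest other 202). Chance is therefore unlikely to account for that count, 1 in 100 being the smallest share that these regroupings can give. Misplaced reads between parent genes and processed pseudogenes may account for part of the calls. Of the genes that separate every distal from every proximal library, 66.7% are processed pseudogenes. Protein-coding genes with a named processed pseudogene were also called more often (18.3%) than those without one (11.3%). The share of such parent genes among the separating genes (8.3%, against 9.1% of all) cannot decide this, because most separating genes are pseudogenes themselves. Misplaced reads cannot account for all calls, because 11.3% of protein-coding genes without a named pseudogene were called. GC content and gene length, a separate explanation, cannot be the whole cause, since 1789 genes were called after their correction. For the T cell markers the values argue against GC content and gene length as the source, since 10 members still fell after the correction. The median of macrophage markers, 0.327 on the log2 scale, argues against a smaller share of all non-epithelial cells, which would need it below 0. Of the T cell markers that fell, 0 have a named processed pseudogene. That says little, since only 1686 of 13122 protein-coding genes tested have one. What could set the pseudogene reads apart by region, such as a processing batch, cannot be told apart from the region itself, since the labels give no batch. A lower density of T cells in the distal epithelium of healthy donors remains a hypothesis, found and tested on the same data.

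The second pattern is the 7896 genes called between EoE and healthy distal biopsies, with cell cycle genes higher. The cell cycle list passed camera with its preset correlation but not with an estimated one. Of 100 splits of the donors, 1, the real one, called as many (highest other 5). Chance is therefore unlikely to account for that count, 1 in 100 being the smallest share that these splits can give. A trend with GC content in the EoE distal libraries cannot be the whole cause, since 5023 calls were kept with the same sign after its correction, and library depth cannot either, since 7637 genes were called with every distal library thinned to the smallest total. After the correction 24 cell cycle genes rose, which argues against the trend as their source. Part of the remaining calls, 6379 after the correction, may still follow a difference in library processing that the labels do not record. The disease, and changes in the mix of cells that come with it, stay open and were not tested apart.

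The third pattern is FTH1, which encodes the ferritin heavy chain and was lower in EoE distal (192.4 ± 237 CPM) than in healthy distal libraries (1451 ± 460 CPM; -2.92 ± 0.56, adjusted p = 0.00018), and was not called in proximal ones (372.9 ± 351 against 805.6 ± 518 CPM; -1.12 ± 0.54, adjusted p = 0.12). The summed CPM of 25 FTH1 pseudogenes was lower in EoE too (-11.6 CPM), so that FTH1 reads counted for pseudogenes do not account for it. Reads assigned to neither cannot be weighed, since the deposited counts hold no lines for unassigned reads. GC content does not account for the fall either, with -2.84 ± 0.56 after the correction. Across the EoE donors FTH1 rose with the squamous differentiation score (r = 0.614 in distal biopsies, permutation p = 0.0047; rho = 0.700, permutation p = 0.0012; r = 0.612 without 2 donors). A loss of FTH1 along with the differentiated layers is a hypothesis that this relation fits, but in healthy donors FTH1 was higher in distal biopsies (0.97 ± 0.18, adjusted p = 0.0056) while the squamous score differed by 0.02, so that the score does not account for that difference. In the healthy donors the summed CPM of the FTH1 pseudogenes went the other way (17.27 ± 5.73 in distal, 32.46 ± 21.7 in proximal biopsies). These values are small beside those of FTH1, but reads assigned to neither cannot be weighed by region. A part of read assignment in the regional difference is therefore not excluded. The regional difference of FTH1 in healthy donors is part of the larger disease effect in distal biopsies (-2.05 ± 0.39, adjusted p = 0.00043), and an iron-related regulation was not tested.

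The remaining counts were also larger than those of every other split. For the 4211 genes of the proximal comparison, 1 of 100 splits called as many (highest other 63). For the 9694 of the EoE regions it was 1 of 40 (highest other 0), and for the 3350 of the difference of the disease effects 1 of 25 (highest other 0). It was the real split in each case. The number of 25 was lowered to save computing time after a longer run was seen. Chance is unlikely to account for these counts, though less firmly so where only 40 and 25 splits were run.

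The disease effect differed between the regions, by the test of the difference itself, for 44 of the genes named, FTH1 included. On the log2 scale, distal minus proximal, it was also lower in distal biopsies for FAM25A (-4.13), EDN3 (-2.92), LAMB4 (-2.65), MT1A (-2.58), PDF (-2.34), DKK1 (-2.19), MT1G (-2.09), MT1M (-1.95), SRXN1 (-1.92), TMEM238 (-1.90), MT1H (-1.89), ENDOG (-1.86), RPS19P1 (-1.85), UQCRFS1P1 (-1.75), TPT1P4 (-1.72), KRTAP3-2 (-1.63), TPGS1 (-1.56), CST6 (-1.46), ALDOA (-1.28), MT2A (-1.28), JUND (-1.18), HSPB1 (-0.97), ENSG00000237214 (-0.94) and BCL3 (-0.42). It was higher for CDH1 (0.31), DSC3 (0.40), KIF11 (0.53), THRAP3 (0.60), DSP (0.71), RAD54L2 (0.72), CENPF (0.77), IRGQ (0.78), POU2F1 (0.81), CD3E (0.83), PRRC2C (0.87), CD3D (0.95), MKI67 (1.07), COL6A3 (1.16), ITGAL (1.22), POMK (1.22), COL12A1 (1.48), IL7R (1.74) and ZFHX4 (2.0). In the fit with the correction for GC content and gene length, chosen after the data were seen, 31 of the 44 were called. Of the 13 that were not, some had much the same estimate: DKK1 (-2.21), MT1G (-1.85), MT1H (-1.71, adjusted p = 0.11), MT1M (-1.58, adjusted p = 0.084), KRTAP3-2 (-1.55), MT2A (-1.13) and CD3E (0.83). The estimates of CST6 (-0.84), JUND (-0.47), CDH1 (0.22), KIF11 (0.38) and DSC3 (0.17) moved towards 0, and BCL3 turned to 0.18.

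Among the healthy groups, the lowest or highest library stood apart by more than Dixon's critical value of 0.526 for 8 samples in 22 of 277 checks (7.9%), and chance does so in about 1 in 20. In distal libraries these were, in log2 CPM, the lowest values of CCL26 (-2.78), ALOX15 (-2.17) and CAPN14 (9.01) and the highest of PDF (1.70). The highest values of IL5 (-2.58), CLC (-2.84), LRRC31 (-2.34) and TGM6 (-2.63) also stood apart there, where the other 7 libraries had 0 counts. Of the distal list scores, the highest of the chemokine list (1.32) and the lowest of the cytotoxic lymphocyte (-1.47) and gastric epithelium (0.04) lists stood apart. In proximal libraries the highest values of IL5 (-2.26), CRNN (14.74), TGM6 (-1.04), IL19 (2.26), KRTAP3-2 (8.08), IRGQ (4.45) and TPT1P4 (4.37) and the lowest of CCL24 (-3.53) and ENDOG (1.90) did so, as did the highest scores of epithelial proteases and inhibitors (9.18) and of type 2 cytokines and receptors (2.66).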

How the results depend on the processing

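The GC corrections, the fits without pseudogene-related genes, the thinned libraries and the similarity with separate donors were chosen after the data were seen. Of 3990 values of named genes under the alternatives, 3570 kept their direction and their side of the threshold, as did 57 of 57 list scores, with the prior count as the 1 alternative, and 15 of 16 correlations by r. By rho, the eosinophil scores of the 2 regions lost their call with a prior count of 0.5 (adjusted p = 0.069), and distal eosinophil against squamous scores gained one with z-scored members (adjusted p = 0.046). The count of the distal disease comparison stayed within 1.5 times of 7896 in every alternative run (5818 to 8663, 7163 to 7544 leaving out each healthy donor). Leaving out 1 donor gave 3144 to 3838 genes in the proximal disease comparison, 9330 to 9801 between the regions in EoE and 2590 to 3754 for the difference of the disease effects. Between the regions in healthy donors it gave 1364 to 2624, with 1364 without HC replicate 3 and 1427 without HC replicate 8, against 2152. The replicate number as a block left 166 genes in the proximal disease comparison and 6267 in the distal one. The numbers pair no samples across disease states (r over 0.1 for 2 of 8 numbers in distal and 0 of 8 in proximal biopsies). Replicate numbers above 8 occur only in EoE, so that this block absorbs those EoE libraries whole. The fit then compares 8 EoE with 8 healthy libraries in arbitrary pairs, and its counts are no check on the full comparison. The cause of the larger loss in the proximal comparison was not tested. Without the block that pairs the biopsies of a donor, 1156 genes were called between the regions in healthy donors and 1510 for the difference of the disease effects, which is a comparison with less power by construction. For that difference 2226 were called with no low-count filter and 1678 with the correction for GC content and gene length with the replicate block. In healthy donors 1101 were called between the regions among protein-coding genes without a named pseudogene, with fewer genes tested. In the distal disease comparison 52.6% of the calls were higher in EoE, but 46.3% with the donor as a random effect and 49.5% with limma-trend, and of the genes changed at least 2-fold 673 were higher and 1311 lower, and 734 higher and 990 lower. In the proximal disease comparison 59.1% of the calls were higher in EoE, 69.9% with no filter and 46.4% in the fit of all libraries with the donor as a random effect. The median log2 change of all genes there was 0.010, 0.124 with no filter and -0.188 with DESeq2, where genes with few counts were tested too, and the cause was not tested.

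Signs turned for these results, and the cause was not tested. With the GC correction and the replicate block, BCL3 (0.17, adjusted p = 0.045), IRF7 (0.28), RAMP1 (0.23), PTGDR2 (0.14), CD79B (0.09), SOCS1 (0.07) and TRAF2 (0.02) turned between the regions in EoE, and BCL3 (0.18) for the difference of the disease effects. Without the block SMPD3 (0.04) and KRT8 (0.10) turned there. In the distal disease comparison the gastric genes AGR2 and GKN1 turned with DESeq2 (-0.48 and -0.60), limma-trend (-0.13 and -2.05) and the random donor effect (-0.15 and -2.98), and GKN1 with the replicate block (-0.98). The proximal correlation of eosinophil and squamous scores was -0.449 with z-scored members and no longer passed. With an estimated correlation, camera passed 0 lists in each of the 5 comparisons, against 9, 9, 4, 1 and 6 with the preset one, and 3 in place of 1 after the GC correction between the regions in EoE. The similarity of the disease effects was 0.599 and 0.732 with no shared donors. Low counts limit IL5 and CLC, with 1 to 3 counts over all healthy libraries of a region.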

Other observations

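The correlations with metallothioneins and with FTH1 and the choice of FTH1, FTL and the metallothioneins were made after their values were seen, and all other values in this part come from lists and tests fixed before the data were examined. Several fixed lists showed changes that the comparisons above do not describe. Of all genes tested, 4154 of 17573 rose and 3742 fell in distal EoE biopsies, and 2489 of 17987 rose and 1722 fell in proximal ones. A count of members near these shares says nothing particular about its list. Nerve and sensory genes had higher scores in EoE in both regions, by 0.57 in distal (permutation test, adjusted p = 0.00065) and 0.70 in proximal biopsies (permutation test, adjusted p = 0.00088), with 4 of 12 members risen and 1 fallen in distal and 3 of 12 risen and 1 fallen in proximal biopsies. The neurotrophin receptor NTRK2 rose 10.2-fold in distal and 7.65-fold in proximal biopsies. Among fibroblast and matrix genes, 7 of 25 rose and 1 fell in distal and 2 of 24 rose and 3 fell in proximal biopsies, with the collagen cross-linking enzyme LOX at 13.4-fold and 9.62-fold and the collagen COL8A2 higher by 2.05 and 1.93 on the log2 scale. The gland list had 2 of 7 members risen and 1 fallen in distal biopsies and 1 of 7 risen in proximal ones, the iron-binding protein LTF at 90.6-fold and 44.4-fold. The chemokine CCL24 rose 9.77-fold and 7.18-fold, within a chemokine list with 3 of 8 and 2 of 8 members risen.

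Besides FTH1, the ferritin light chain FTL fell in distal EoE biopsies by 0.81 on the log2 scale (adjusted p = 8.6e-05), and so did the metallothioneins MT2A (-2.91 ± 0.51, adjusted p = 7.7e-05) and MT1G (-3.50 ± 0.9, adjusted p = 0.0028). In proximal biopsies FTL (-0.32, adjusted p = 0.13), MT2A (-1.06, adjusted p = 0.18) and MT1G (-1.60, adjusted p = 0.18) were not called. Across the EoE donors the mean of 8 metallothioneins rose with the squamous differentiation score, with r = 0.669 in distal (permutation p = 0.0015; rho = 0.730, permutation p = 0.00065; r = 0.661 without 2 donors) and r = 0.777 in proximal biopsies (permutation p = 4e-05; rho = 0.800, permutation p = 7e-05; r = 0.771 without 2 donors). FTH1 did so in proximal biopsies as well, with r = 0.789 (permutation p = 7e-05; rho = 0.725, permutation p = 0.00056; r = 0.686 without 2 donors).

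NF-kappaB genes, the pathway of IKBKB, moved both ways. Of 20 pathway components 9 rose and 5 fell in distal and 6 rose and 3 fell in proximal biopsies, and RELA, the main transactivating subunit, fell in both (-0.46 ± 0.06, adjusted p = 1.9e-06, and -0.43 ± 0.079, adjusted p = 0.0013). Of 22 NF-kappaB targets 5 rose and 7 fell in distal biopsies, and of 23 in proximal ones 4 rose and 4 fell, with score differences of 0.02 and 0.00. Macrophage markers rose in 7 of 13 cases in distal biopsies, with MRC1 at 5.96-fold, B and plasma cell markers in 4 of 9 and 3 of 6, dendritic cell markers in 4 of 14 and in 5 of 14 with 1 fallen, and endothelial markers in 5 of 17 with 1 fallen and in 2 of 17 with 1 fallen. Neutrophil markers fell in 2 of 7 cases in distal biopsies, and none of 6 was called in proximal ones. Hypoxia response genes fell in 9 of 19 and rose in 2 in distal, and rose in 3 and fell in 1 in proximal biopsies. Basal keratinocyte genes rose in 3 and fell in 4 of 20 in distal and rose in 1 and fell in 3 in proximal biopsies, junction genes rose in 4 and fell in 5 of 22 and rose in 3 and fell in 2, and epithelial proteases and inhibitors fell in 7 and rose in 3 of 24 and fell in 1 and rose in 3, with the cystatin CST6 falling by 2.31 in distal biopsies. Immediate early and heat shock genes rose in 1 and fell in 4 of 20 in distal and rose in 4 in proximal biopsies. Genes near risk loci rose in 5 and fell in 1 of 10 and rose in 3 and fell in 1. The median of the NF-kappaB targets was below 0 and their mean above it in both regions, and camera's direction was downward. Interferon response genes rose in 4 of 23 cases in proximal biopsies, IFI27 by 5.88-fold. Smooth muscle markers rose in 1 of 5 in distal biopsies.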
